A study of Mus musculus with 15 samples.

How the data were processed

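The values used here are the deposited table of the authors. That they are log2 intensities was read from their range and is not stated by the labels. The authors had quantile-normalized the log2 values between arrays before they were deposited, as the values themselves show: the sorted values of any 2 arrays differed by at most 0.01 and all 15 medians were 6.92. The lowest value was 6.52 and the values were written with 2 decimals. The pile of dim probes lay far above 0 on this scale, which is how unsubtracted background looks, so no background had been subtracted or an offset was left. The software of the authors is not stated. Per the labels' protocols, RNA was isolated with TRIsure and the NucleoSpin RNA II kit, checked on a Bioanalyser, and amplified and biotin-labelled with an Ambion kit. A second table of raw signals has 15 sample columns whose names match no label, so it was not used here.

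The design fixed before the data were examined had named that raw table, with neqc and its detection p-values. The values of the authors took its place, and a background level took the place of the detection p-values. The mode of all values, 6.80, was taken as the background and the values below it gave its SD of 0.0718 by reflection. A probe was tested when it exceeded 6.92, the 95% limit of this background, on at least 5 of 15 arrays. The groups, comparisons, tests, gene lists and rule for naming genes were also fixed before the data were examined.

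Probe symbols came from the platform table. Of 45281 probes, 34885 carry 1 symbol, 18 carry several and 10378 carry none. Probes without a symbol were tested and counted but not named. The gene identifiers of 34807 probes were found in a table of mouse genes, and 0 symbols had to be updated. The tested 24861 probes include 20429 with a symbol.

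One linear model with a mean per group was fitted to the 15 arrays with limma 3.58.1 in R 4.3.3, with 12 residual degrees of freedom and a variance trend over intensity. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Gene lists, 58 in number with 1135 of their 1137 genes on the arrays, were tested with camera of limma at a preset correlation between genes of 0.01, using the brightest probe of each gene. The 56 lists with at least 5 tested genes entered the test, and camera with an estimated correlation and fry were run beside it. The Vegfb probe was also compared by an exact two-sided permutation test. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

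Genes were named by rule. Vegfb, Flt1, Nrp1 and Kdr were named in each comparison. So were the 10 largest rises and the 10 largest falls past the threshold, provided that the probe lay above background on all arrays of the higher group, that the groups did not overlap and that the symbol was a proper one, with 1 probe per gene. For up to 8 lists of smallest p, up to 3 members of smallest p were named, those past the threshold first. For lists of cell type markers the 2 brightest members were given as values. A gene named on other grounds is said to have been chosen after its values were seen.

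The procedure was also run on simulated arrays with known changes, drawn from the normal distribution with the mean and residual SD of each probe and no correlation between probes, with 50 changed probes at each of 4 sizes. Real arrays share variation between genes, so these figures are a best case. Of log2 folds of 0.25, 0.5, 1 and 2 it recovered 30%, 80%, 98% and 98% in DOX against PBS, 52%, 88%, 100% and 100% in VEGFB_DOX against DOX, and 32%, 86%, 90% and 100% in VEGFB_DOX against PBS. False calls were 5 of 158, 8 of 178 and 10 of 164. A list shifted by 0.3 was recovered in each comparison with 0 other lists called.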

Results

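Gene expression was measured in myocardium, the muscle of the heart, of male C57Bl/6J mice aged 10 weeks. Each sample was hybridised to 1 Illumina BeadChip array as biotin-labelled cRNA. The 15 samples fell into 3 groups of 5. One group was injected with PBS. One was injected with doxorubicin, an anthracycline chemotherapy drug whose use is limited by damage to the heart (DOX). The third was given AAV9-VEGF-B, an adeno-associated viral vector for vascular endothelial growth factor B, 7 days before the same drug (VEGFB_DOX). Hearts were taken 20 hours after the injection of doxorubicin or PBS. The values are log2 intensities of 45281 probes that the authors had quantile-normalized between arrays, so every array had a median of 6.92, and single values ran from 6.52 to 14.93. They look as if background had not been subtracted or an offset had been left, and where that holds the folds given here understate the change, most of all for dim probes. In all, 24861 probes lay above background on at least 5 arrays and were tested, of which 20429 carry a gene symbol and belong to 12750 genes. Folds are log2 differences between group means ± the standard error of the limma fit, with 5 arrays per group, and p-values are adjusted by the Benjamini-Hochberg method. The number of arrays limits the precision, and the median standard error of a fold was 0.07. The labels describe 5 mice per group. If arrays shared an animal, the p-values would measure only the spread between samples.

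The gene that the vector was made to deliver was examined first, with the receptors of its protein. The single Vegfb probe, ILMN_2450384, read 12.95 ± 0.07 (SD, n = 5) in PBS, 12.98 ± 0.09 in DOX and 12.76 ± 0.07 in VEGFB_DOX hearts. It was thus not higher in the hearts that had received the vector: its signal fell by 0.22 ± 0.06 against DOX (limma, adjusted p = 0.0199) and by 0.19 ± 0.06 against PBS (adjusted p = 0.0449). All 5 VEGFB_DOX arrays lay below every array of the other groups, and the two-sided exact permutation test gave p = 0.00794 for both comparisons, the smallest p that 5 against 5 arrays allow. DOX and PBS differed by 0.04 ± 0.06 (exact permutation test, p = 0.508). Whether this probe lies in the sequence carried by the vector is not known here, so its level checks neither the labels nor the transfer. The adjusted call against DOX ended without DOX 5, at -0.19, and without VEGFB_DOX 2, at -0.20, and that against PBS ended in 8 of the 10 fits that left out an array of either group, with values from -0.20 to -0.16. Among the receptors, Flt1, which encodes the VEGF-B receptor VEGFR1, rose by 0.45 ± 0.08 in VEGFB_DOX against PBS (adjusted p = 0.0014). Its fold against DOX was 0.24 ± 0.08 (adjusted p = 0.0809) and that of DOX against PBS 0.21 ± 0.08 (adjusted p = 0.346), and a second, dim Flt1 probe showed 0.11 in VEGFB_DOX against PBS (adjusted p = 0.377). The co-receptor gene Nrp1 rose against DOX on each of its 3 probes, by 0.59 ± 0.13, 0.59 ± 0.11 and 0.61 ± 0.15 (adjusted p = 0.00586, 0.00132 and 0.0117). In DOX against PBS these probes stood at -0.31, -0.30 and -0.34 (adjusted p = 0.403, 0.295 and 0.405), and without DOX 2 they passed, at -0.47, -0.40 and -0.52. In VEGFB_DOX against PBS they stood at 0.29, 0.29 and 0.26 (adjusted p = 0.183, 0.096 and 0.299), and the first 2 passed with only the 2 groups in the fit (adjusted p = 0.0235 and 0.0335) and without DOX 2 and VEGFB_DOX 3 (adjusted p = 0.0479 and 0.0229). The tested probe of Kdr, which encodes VEGFR2, lay near background, and its folds of -0.03, 0.08 and 0.05 in the 3 comparisons passed no test (adjusted p = 0.861, 0.245 and 0.499).

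**Figure D1:**
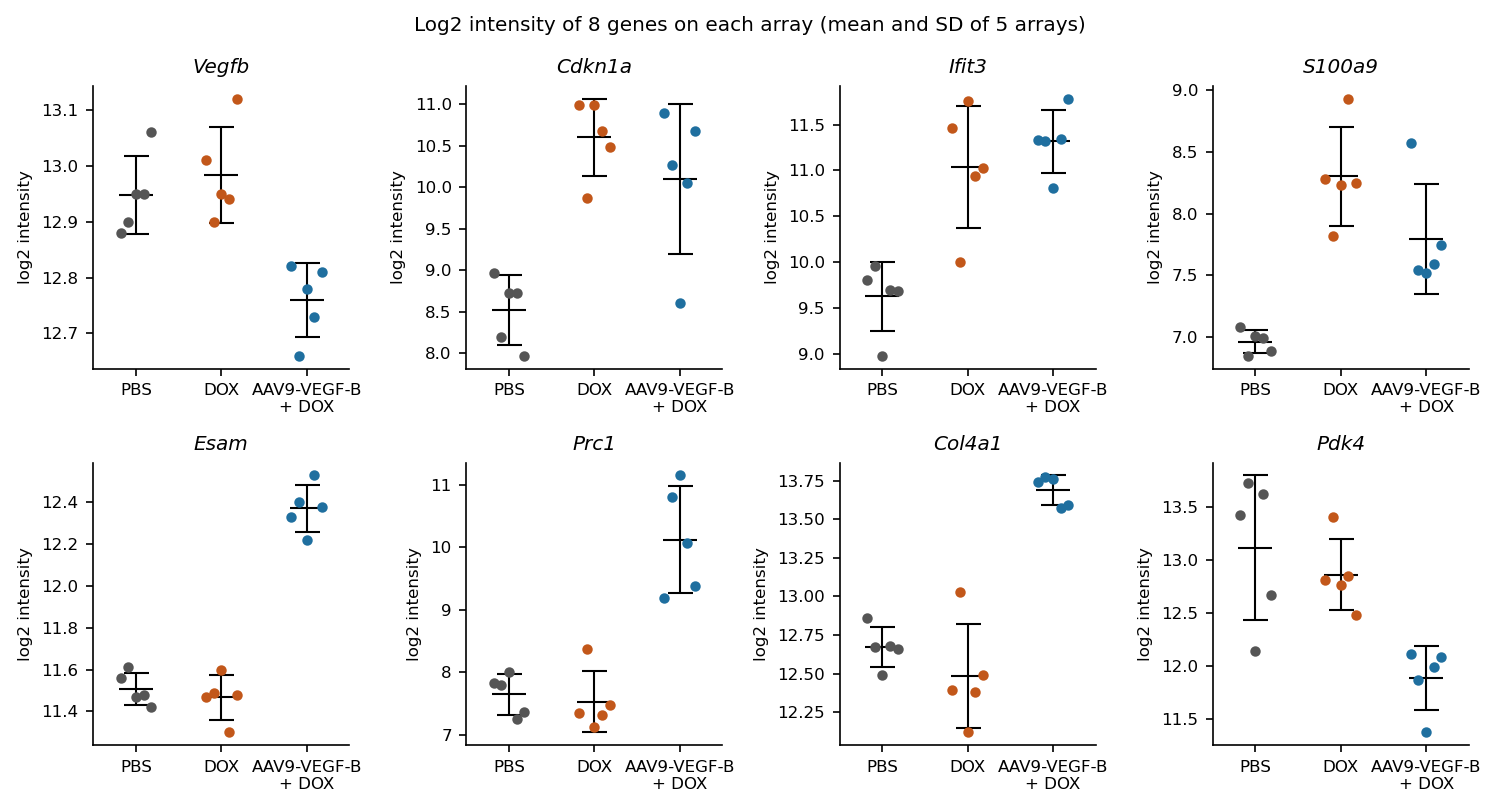
Log2 intensity of 8 genes (y axes) on each array of the 3 groups (x axes), where points are arrays and the bars give the mean and SD of 5 arrays. Cdkn1a and Ifit3 lie higher in both drug groups, with group means of 10.60 and 10.10 against 8.52 for Cdkn1a, while Esam, Prc1 and Col4a1 are higher and Vegfb and Pdk4 lower in the hearts that had also received AAV9-VEGF-B.

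The comparison of DOX with PBS asks what the drug alone had done to the heart after 20 hours. Cdkn1a, the p53 target gene that encodes the cell cycle inhibitor p21, rose from 8.52 ± 0.42 (SD, n = 5) to 10.60 ± 0.46, a log2 fold of 2.08 ± 0.33 or 4.23 times (limma, adjusted p = 0.0106). This call ended without DOX 1 or DOX 3 (1.98 in both) and with a robust variance prior (adjusted p = 0.0527), which also ended those of Ifit3 (adjusted p = 0.0729), Serpina3n (adjusted p = 0.0665) and Ei24 (adjusted p = 0.0604). Genes induced by interferon rose too: Ifit3 by 1.41 ± 0.25 (adjusted p = 0.0283), Oasl2 by 1.31 ± 0.21, Usp18 by 1.06 ± 0.17 and the guanylate-binding protein gene Gbp3 by 0.97 ± 0.17. The Ifit3 call also ended without any 1 of PBS 3, PBS 4, PBS 5, DOX 1, DOX 3 and DOX 4 (1.23 to 1.43). S100a9 and S100a8, whose products form calprotectin in neutrophils, rose by 1.34 ± 0.18 and 1.18 ± 0.18, from a PBS signal that lay above background on 3 and on 2 of 5 arrays. Dbp, a transcription factor gene driven by the circadian clock, fell by 1.85 ± 0.37 (adjusted p = 0.0388), a call that ended with a robust variance prior or one without trend (adjusted p = 0.12 and 0.0615) and without any 1 of PBS 2, PBS 4, PBS 5, DOX 1, DOX 3 and DOX 4 (-2.01 to -1.54). The next falls by size were those of the dynein assembly factor gene Dnaaf3 at -0.94 ± 0.13, of Ttll1 at -0.77 ± 0.14 and of Tmem86a at -0.72 ± 0.12. The other genes among the 10 largest rises were the chemokine gene Ccl12 (1.20), Cnksr1 (0.80) and the acute-phase gene Serpina3n (0.80). Among the 10 largest falls, Igdcc4, the cGMP-dependent kinase gene Prkg1, the cytokine gene Ctf1, the water channel gene Aqp4, the potassium channel gene Kcnd2 and the phosphatase gene Dusp23 lay between -0.54 and -0.49. Other probes of Prkg1 (0.08 and -0.10), Aqp4 (-0.03) and Igdcc4 (-0.11) did not pass the test.

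Over all probes, 80 passed the adjusted threshold in DOX against PBS, 56 higher and 24 lower, which belong to 37 and 19 named genes. Of these, 10 rose and 1 fell by at least 2-fold, and 2559 probes had an unadjusted p under 0.05. Of the 56 gene lists that were fixed before the data were examined and had enough tested genes, 13 lay higher and 3 lower with a preset correlation between genes, and 2 of them also with an estimated one. The 3 lower lists became 6 without DOX 2 and 8 without DOX 2 and VEGFB_DOX 3. Type I interferon response genes rose the most as a group: 8 of 23 rose and 21 of 23 when adjusted over the list alone. Their median was 0.68 (adjusted p = 3.06e-31, and adjusted p = 0.0778 with an estimated correlation). The antiviral membrane protein gene Ifitm3 rose by 0.65 ± 0.10. Of 34 p53 target genes, 3 rose, namely Cdkn1a, Phlda3 (0.77 ± 0.15) and Ei24 (0.62 ± 0.13), and 9 rose when adjusted over the list alone. Their median was 0.19 (adjusted p = 8.34e-12, and adjusted p = 0.219 with an estimated correlation). The mean of the p53 list relative to PBS was 0.02 on the array DOX 2, inside the range of the PBS arrays (-0.01 to 0.03), and 0.30 to 0.52 on the other 4 DOX arrays. The interferon list showed the same order, with 0.20 on DOX 2 and 0.67 to 1.05 on the other 4. Of 9 neutrophil marker genes, S100a8 and S100a9 rose and 6 rose when adjusted over the list alone. Their median was 0.16 (adjusted p = 5.22e-07), a call that held with an estimated correlation (adjusted p = 0.0288). The other list whose call held so was that of calcium handling and excitation, which fell as a group with a median of -0.13 (adjusted p = 7.01e-04, and adjusted p = 0.0315 with an estimated correlation). None of its 22 genes passed alone on the probes used for the lists and 6 fell when adjusted over the list alone, for example Kcnd2 at -0.64 ± 0.18 on its brighter probe (adjusted p = 0.14) and the channel subunit gene Kcnip2 at -0.34 ± 0.10 (adjusted p = 0.158).

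Further lists were called in DOX against PBS, and these calls were lost with an estimated correlation. None of 15 replication-dependent histone genes passed alone, and 7 rose when adjusted over the list alone. Their median was 0.29 (adjusted p = 1.97e-05, and adjusted p = 0.23 with an estimated correlation). None of 23 NRF2 target genes of the antioxidant response passed alone and 3 rose when adjusted over the list alone, with a median of 0.13 (adjusted p = 2.55e-05, and adjusted p = 0.178 with an estimated correlation). The sulfiredoxin gene Srxn1 stood at 0.33 ± 0.09 (adjusted p = 0.152). None of 12 complement genes passed alone and 2 rose when adjusted over the list alone. Their median was 0.16 (adjusted p = 4.28e-04, and adjusted p = 0.219 with an estimated correlation). Of 22 acute-phase genes S100a8, S100a9 and Serpina3n rose, and 5 rose and 1 fell when adjusted over the list alone. Their median was 0.10 (adjusted p = 7.54e-04, and adjusted p = 0.221 with an estimated correlation). Of 20 glucocorticoid-induced genes the only one to rise was Cdkn1a, which is also a p53 target, and 3 rose when adjusted over the list alone. Their median was 0.18 (adjusted p = 7.01e-04, and adjusted p = 0.394 with an estimated correlation). Markers of smooth muscle and pericytes fell as a group with a median of -0.17 over 15 genes (adjusted p = 2.13e-04, and adjusted p = 0.243 with an estimated correlation). The potassium channel gene Kcnj8 was the 1 member that fell, by 0.35 ± 0.07, also when adjusted over the list alone. Its call ended without any 1 PBS array and without DOX 1, DOX 3 or DOX 4 (-0.37 to -0.32), without a filter on dim probes (adjusted p = 0.0794), with only the 2 groups (adjusted p = 0.0835) and with the replicate number in the model (adjusted p = 0.0631). The 2 brightest members, Acta2 and Des, both stood at -0.08 (adjusted p = 0.912 and 0.788). No member of the 23 macrophage markers passed alone and 1 rose when adjusted over the list alone. Their median was 0.08 (adjusted p = 0.00415, and adjusted p = 0.579 with an estimated correlation), and the call ended without PBS 4 (median 0.06, adjusted p = 0.0948). The brightest members C1qb and Lgmn stood at 0.42 ± 0.13 and 0.18 ± 0.10. Markers of endothelial cells (median 0.002, adjusted p = 0.41, Aqp1 0.27 and Egfl7 0.008) and of ventricular cardiomyocytes (median -0.05, adjusted p = 0.13, Tnnc1 -0.09 and Fabp3 -0.14) did not pass the list test with camera. With fry the ventricular list was lower (adjusted p = 0.0472). The haemoglobin genes Hbb-bs and Hbb-bt, near-identical copies whose probes cannot be told apart with certainty, stood at -0.51 ± 0.24 and -0.47 ± 0.23 (adjusted p = 0.47 and 0.499). The erythroid list mean was 0.14 on DOX 2 and -0.36 to -0.20 on the other 4 DOX arrays.

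The number of probes that passed in DOX against PBS moved with single arrays: it was 487 without DOX 2, 2 without DOX 1, 11 without DOX 3, 21 without DOX 4, 26 without PBS 2, 28 without PBS 3, 17 without PBS 4 and 22 without PBS 5, and of the 24 named probes that passed 2 also passed without DOX 1 and 7 without DOX 3. It was 677, with all 80 among them, when both DOX 2 and VEGFB_DOX 3 were left out, 201 with array weights, 53 without a variance trend and 1 within the 11 arrays that remained when PBS 4, PBS 5, DOX 5 and VEGFB_DOX 5, set apart by the second principal component, were left out. The split into higher and lower probes moved as well, to 269 and 218 without DOX 2, 361 and 316 without DOX 2 and VEGFB_DOX 3, 110 and 91 with array weights, 41 and 38 without DOX 5 and 15 and 13 without PBS 3.

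**Figure D2:**
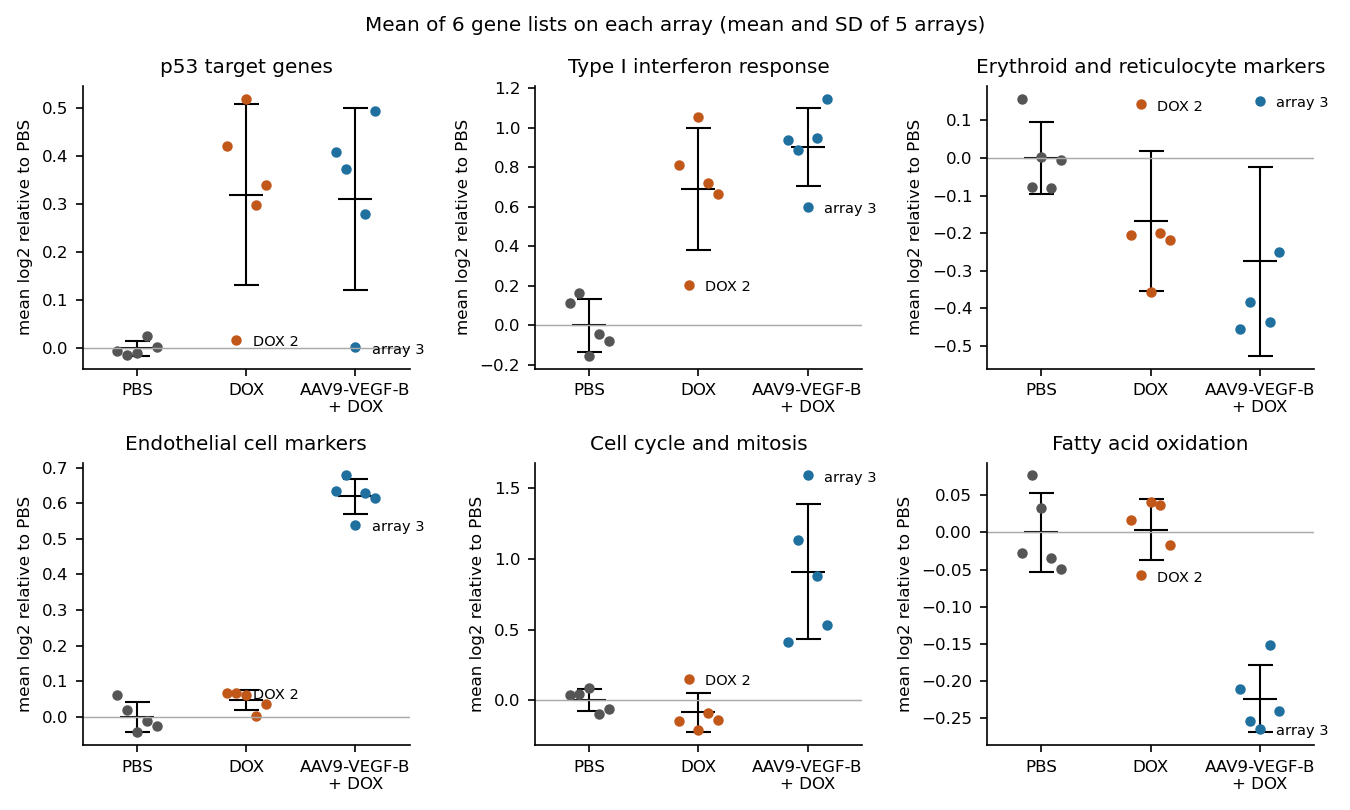
Mean log2 value of 6 gene lists relative to the PBS mean (y axes) on each array of the 3 groups (x axes), where points are arrays and the bars give the mean and SD of 5 arrays. The p53 target genes of DOX 2 (0.02) and of the third VEGFB_DOX array (0.002) lie at the PBS level, the endothelial markers of all 5 VEGFB_DOX arrays lie at 0.54 or above, and the fatty acid oxidation genes are lower in that group.

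The comparison of VEGFB_DOX with DOX asks what AAV9-VEGF-B, given before the drug, added to its effect; vector and VEGF-B were not separated, since every heart of this group had received both. Endothelial genes rose: the endothelial cadherin gene Cdh5 by 1.20 ± 0.11 (limma, adjusted p = 1.53e-06), the junction gene Esam by 0.90 ± 0.07 (adjusted p = 3.68e-07), Icam2 by 0.94 ± 0.09 and the apelin receptor gene Aplnr by 1.80 ± 0.22. Genes of cell division rose with them, led by the cytokinesis gene Prc1 at 2.59 ± 0.31 or 6.03 times (adjusted p = 2.15e-05), and by Kif23 at 1.79 ± 0.29 and Cdc20 at 1.54 ± 0.18. Col18a1, which encodes a collagen of basement membranes, rose by 1.69 ± 0.11 (adjusted p = 4.88e-08) and the actin-bundling gene Fscn1 by 1.59 ± 0.24. Part of the Aplnr and Fscn1 folds comes from DOX arrays that read low against PBS. Aplnr read 8.85 to 10.69 in DOX and 10.39 to 10.73 in PBS, and Fscn1 7.99 to 9.59 and 8.74 to 9.26. The same holds for Ets1, at 10.79 to 11.46 and 11.36 to 11.69. Among the largest falls, Pdk4, a kinase that restrains glucose oxidation, fell by 0.97 ± 0.25 (adjusted p = 0.0162), Acot1 by 0.78 ± 0.19, Retsat by 0.64 ± 0.13, Fbp2 by 0.61 ± 0.10 and the malonyl-CoA decarboxylase gene Mlycd by 0.55 ± 0.11. Dbp rose by 1.62 ± 0.37, where the DOX arrays that enter this fold are those of its fall against PBS. The histone genes H2ac7, H2ac24, H2ac13 and H2ac10 stood among the largest rises at 1.79, 1.78, 1.73 and 1.68, but they are near-identical copies whose probes cannot be told apart with certainty. All 4 peaked on VEGFB_DOX 3 (11.89 to 12.92), and without it their folds were 1.25, 1.27, 1.18 and 1.10. Further falls were those of Txlnb (-0.68), Tesc (-0.56), Ephx2 (-0.55), Ddo (-0.55) and Slc41a3 (-0.55). Other probes disagreed for Ets1, at 0.05 against 1.20, and for Fn1, at 0.17 against 1.05, where the weaker probe did not pass.

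In all, 2383 probes passed in VEGFB_DOX against DOX, 1595 higher and 788 lower, which belong to 1147 and 601 named genes. Of these, 96 rose and 2 fell by at least 2-fold. Of the 56 lists, 13 lay higher and 9 lower, and 5 of them also with an estimated correlation. Of 27 endothelial markers 19 rose and 20 when adjusted over the list alone. Their median was 0.59 (adjusted p = 2.02e-21, and adjusted p = 2.11e-05 with an estimated correlation). Their brightest members were Aqp1, which did not pass at 0.01 ± 0.14 (adjusted p = 0.976), and Egfl7, which rose by 0.81 ± 0.09. Of 21 genes of angiogenic tip cells 15 rose and 16 when adjusted over the list alone, with a median of 0.56 (adjusted p = 7.04e-15, and adjusted p = 9.88e-04 with an estimated correlation). They include the basement membrane gene Nid2 (1.30 ± 0.11), the transcription factor gene Ets1 (1.20 ± 0.12) and the growth factor gene Pdgfb (0.72 ± 0.07). Of 13 Notch signalling genes 6 rose and 7 when adjusted over the list alone, with a median of 0.28 (adjusted p = 1.03e-07, and adjusted p = 0.00167 with an estimated correlation). Among them were Notch4 (0.92 ± 0.08), Hey1 (1.16 ± 0.11) and Nrarp (0.91 ± 0.12). Of 20 genes of endothelial lipid handling and nitric oxide 9 rose and 11 when adjusted over the list alone. Their median was 0.33 (adjusted p = 6.24e-06, and adjusted p = 0.00216 with an estimated correlation). They include Nos3, the endothelial nitric oxide synthase, at 0.96 ± 0.10, Gpihbp1, which carries lipoprotein lipase to the capillary lumen, at 0.70 ± 0.09, and Cav1 at 0.79 ± 0.12. Fatty acid oxidation genes went the other way: 7 of 23 fell and 11 when adjusted over the list alone, with a median of -0.23 (adjusted p = 9.72e-06, and adjusted p = 0.00373 with an estimated correlation). Cpt2 fell by 0.31 ± 0.06, Etfb by 0.27 ± 0.06 and Acadvl by 0.23 ± 0.05.

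The remaining lists called in VEGFB_DOX against DOX were not called with an estimated correlation. Of 18 cell cycle and mitosis genes 17 rose and all 18 when adjusted over the list alone, with a median of 1.02 (adjusted p = 1.79e-17, and adjusted p = 0.116 with an estimated correlation). The list mean was highest on VEGFB_DOX 3, at 1.59 against 0.41 to 1.14 on the other 4. Of 26 genes of extracellular matrix and TGF-beta response 16 rose and 19 when adjusted over the list alone, with a median of 0.49 (adjusted p = 7.68e-14, and adjusted p = 0.0958 with an estimated correlation). Col4a1 and Col4a2, the collagens of basement membranes, rose by 1.20 ± 0.12 and 1.16 ± 0.11 and the fibronectin gene Fn1 by 1.05 ± 0.10. Of 15 smooth muscle and pericyte markers 8 rose, and 9 rose and 1 fell when adjusted over the list alone. Their median was 0.33 (adjusted p = 8.62e-06, and adjusted p = 0.156 with an estimated correlation). The members of smallest p were Higd1b at 0.85 ± 0.09, Pdgfrb at 0.64 ± 0.08 and Kcnj8 at 0.50 ± 0.07, while Acta2 stood at 0.24 and Des at -0.17 (adjusted p = 0.414 and 0.203). Of 18 PPAR-alpha target genes 4 fell and 6 when adjusted over the list alone. Their median was -0.21 (adjusted p = 6.30e-04, and adjusted p = 0.107 with an estimated correlation). Of 20 fibroblast markers 5 rose, and 10 rose and 1 fell when adjusted over the list alone, with a median of 0.295 (adjusted p = 0.00103, and adjusted p = 0.268 with an estimated correlation). The brightest members Dcn and Ogn stood at 0.09 and -0.05 (adjusted p = 0.476 and 0.835). Of 23 macrophage markers 4 rose and 5 when adjusted over the list alone, with a median of 0.20 (adjusted p = 7.15e-04, and adjusted p = 0.436 with an estimated correlation). Lgmn stood at 0.10 and C1qb at 0.29 (adjusted p = 0.649 and 0.196). Type I interferon genes, already higher in DOX, had a median of 0.19 (3 of 23 rose, also when adjusted over the list alone, adjusted p = 0.00479, and adjusted p = 0.564 with an estimated correlation), and this call ended without DOX 2 (median 0.06, adjusted p = 0.206). The p53 target genes did not move as a group: 4 of 34 rose and 3 fell, also when adjusted over the list alone, with a median of -0.05 and a mean of -0.01 where the list test pointed up (adjusted p = 0.909). The list of replication-dependent histones, whose tested members do not include the 4 H2ac genes named above, went down: none of 15 passed alone, also when adjusted over the list alone, and the median was -0.22 (adjusted p = 0.00685, and adjusted p = 0.436 with an estimated correlation). NRF2 targets went down as well, where 1 of 23 rose and 5 fell, and 1 rose and 6 fell when adjusted over the list alone, with a median of -0.14 (adjusted p = 0.0151, and adjusted p = 0.327 with an estimated correlation). Both calls ended without DOX 3 (medians of -0.144 and -0.132, adjusted p = 0.0579 for each). The p53 target Cdkn1a itself stood at -0.50 ± 0.33 (adjusted p = 0.41), a fold that rested on VEGFB_DOX 3, which read 8.60 against 10.05 to 10.89 on the other 4, and without it the fold was -0.13 ± 0.23 (adjusted p = 0.827). Ventricular cardiomyocyte markers had a median of 0.01 (adjusted p = 0.694), with Tnnc1 at 0.09 and Fabp3 at 0.11. Of 8 lymphatic markers, Ccl21a fell by 0.42 ± 0.12 (adjusted p = 0.0278), Prox1 by 0.44 ± 0.09 (adjusted p = 0.00484) and Reln by 0.46 ± 0.11 while Thy1, which T cells and fibroblasts also express, rose by 1.33 ± 0.15. The same members passed when adjusted over the list alone, and the list as a whole passed no test (median -0.16, adjusted p = 0.441); Reln and Thy1 were named after their values were seen.

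Leaving out any single array moved the total for VEGFB_DOX against DOX by less than 1.5 times, but the 788 lower probes became 411 without DOX 4, 429 without VEGFB_DOX 2, 479 without VEGFB_DOX 3, 517 without VEGFB_DOX 1, 505 without a filter on dim probes, and 1401 with the 4 arrays of the second component as a block, while array weights gave 3601 probes in all with 1550 lower, and cyclic loess between arrays gave 2301 with another split of 1770 higher and 531 lower. Of the named genes, Pdk4 was not called without DOX 2 and VEGFB_DOX 3 (-0.71, adjusted p = 0.0992) or with a robust variance prior (adjusted p = 0.0504), which also ended the calls of H2ac13 and H2ac10 (adjusted p = 0.0523 and 0.0737), H2ac10 was not called without DOX 1, DOX 4 or VEGFB_DOX 4 (1.63, 1.60 and 1.61), and Ccl21a was not called without DOX 1, DOX 2, DOX 4, VEGFB_DOX 1 or VEGFB_DOX 3 (-0.42, -0.36, -0.42, -0.39 and -0.34).

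**Figure D3:**
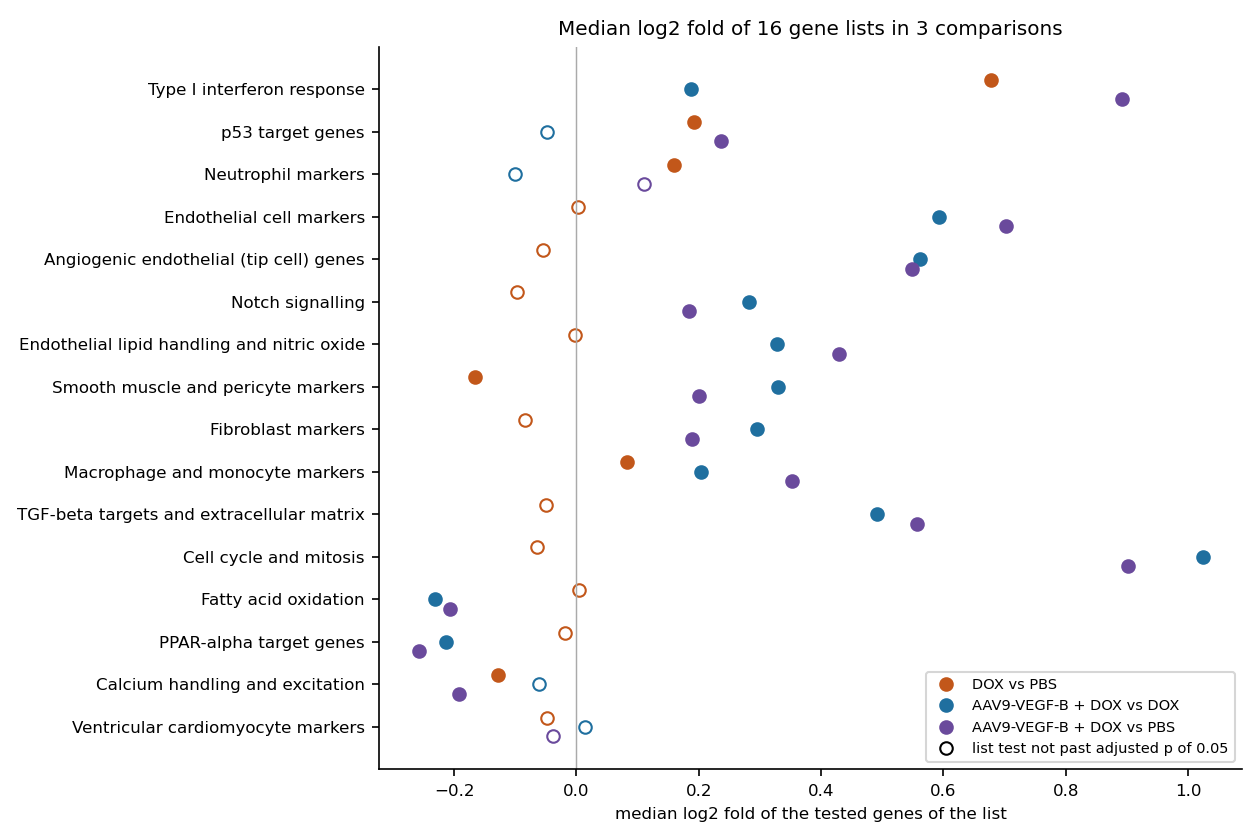
Median log2 fold (x axis) of the tested genes of 16 gene lists (y axis) in the 3 comparisons, where a filled circle marks a list test past an adjusted p of 0.05 with the preset correlation and an open circle one that was not. Interferon genes have medians of 0.68 in DOX and 0.89 in VEGFB_DOX against PBS, and endothelial markers 0.002 and 0.70.

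The comparison of VEGFB_DOX with PBS gives the vector, VEGF-B and drug together. Prc1 rose by 2.47 ± 0.31 (limma, adjusted p = 4.28e-05), Kif23 by 1.54 ± 0.29, Cdc20 by 1.51 ± 0.18 and Col18a1 by 1.46 ± 0.11 (adjusted p = 5.66e-07). The intermediate filament gene Vim rose by 1.45 ± 0.11 and the imprinted gene Mest by 1.40 ± 0.16. The interferon genes Ifit3, Irf7, Oasl2 and Usp18 rose by 1.69 ± 0.25, 1.55 ± 0.22, 1.44 ± 0.21 and 1.42 ± 0.17. Inmt, an indole methyltransferase gene, fell by 1.35 ± 0.24 (adjusted p = 9.94e-04), Pdk4 by 1.22 ± 0.25 and the pyruvate dehydrogenase phosphatase gene Pdp2 by 0.84 ± 0.10. The other large falls were those of Tmem82, Tbc1d10c, Dnaaf3, Lrg1, Ky, Txlnb and Itgb6, from -0.95 to -0.81, where a second probe of Tbc1d10c showed -0.02 and did not pass. The p53 target Cdkn1a rose by 1.58 ± 0.33 (adjusted p = 0.00368), and by 1.95 ± 0.23 without VEGFB_DOX 3.

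In all, 2841 probes passed in VEGFB_DOX against PBS, 1671 higher and 1170 lower, which belong to 1192 and 864 named genes, and 79 rose and 3 fell by at least 2-fold. Of the 56 lists, 19 lay higher and 6 lower, and 7 of them also with an estimated correlation. Of 27 endothelial markers 22 rose and 23 when adjusted over the list alone, with a median of 0.70 (adjusted p = 6.51e-24, and adjusted p = 1.16e-05 with an estimated correlation). Esam, Icam2 and Mmrn2 rose by 0.86, 0.94 and 0.78, Egfl7 by 0.81, and Aqp1 stood at 0.28 (adjusted p = 0.246, and 0.0286 without VEGFB_DOX 3). Tip cell genes (14 of 21 rose, also when adjusted over the list alone, median 0.55, adjusted p = 0.00196 with an estimated correlation), among them Nid2 at 1.26 and Sox18 at 0.89, rose too. So did Notch signalling genes (6 of 13, also when adjusted over the list alone, median 0.18, adjusted p = 0.00792 with an estimated correlation) and genes of endothelial lipid handling and nitric oxide (11 of 20 rose, and 12 rose and 1 fell when adjusted over the list alone, median 0.43, adjusted p = 0.00299 with an estimated correlation). Of 23 fatty acid oxidation genes 9 fell and 12 when adjusted over the list alone, with a median of -0.21 (adjusted p = 0.00684 with an estimated correlation). Of 22 genes of calcium handling and excitation 6 fell and 1 rose, and 7 fell and 1 rose when adjusted over the list alone, with a median of -0.19 (adjusted p = 0.0289 with an estimated correlation). Of 21 cytosolic ribosomal protein genes 3 rose, also when adjusted over the list alone, with a median of 0.15 (adjusted p = 0.0302 with an estimated correlation). Type I interferon genes rose in 21 of 23, also when adjusted over the list alone, with a median of 0.89 (adjusted p = 3.22e-20, and adjusted p = 0.0878 with an estimated correlation). Ifitm3 rose by 1.02 and Rsad2 by 1.36. Cell cycle genes (17 of 18 rose, also when adjusted over the list alone, median 0.90, adjusted p = 3.20e-14, and adjusted p = 0.14 with an estimated correlation) included Top2a, a topoisomerase that doxorubicin poisons, at 1.05 ± 0.15, from a PBS signal above background on 2 of 5 arrays. Matrix genes (14 of 26 rose and 18 when adjusted over the list alone, median 0.56, adjusted p = 4.81e-12, and adjusted p = 0.0921 with an estimated correlation) had Fn1 at 1.02 and Col4a1 at 1.01. Of 23 macrophage markers 11 rose and 16 when adjusted over the list alone, with a median of 0.35 (adjusted p = 2.79e-07, and adjusted p = 0.209 with an estimated correlation). The complement genes C1qb and C1qc rose by 0.71 ± 0.13 and 0.55 ± 0.13 and the receptor subunit gene Fcer1g by 0.66 ± 0.13, while the bright member Lgmn stood at 0.27 (adjusted p = 0.0937). Genes of interferon gamma and antigen presentation (14 of 28 rose and 17 when adjusted over the list alone, median 0.30, adjusted p = 3.94e-07, and adjusted p = 0.12 with an estimated correlation) included H2-D1 at 0.83 and Psmb9 at 0.71. Of 34 p53 targets 11 rose, and 16 rose and 1 fell when adjusted over the list alone, with a median of 0.24 (adjusted p = 1.70e-05, and adjusted p = 0.334 with an estimated correlation). The list mean was 0.002 on VEGFB_DOX 3 and 0.28 to 0.49 on the other 4. Hbb-bs and Hbb-bt fell by 0.81 ± 0.24 and 0.77 ± 0.23 (adjusted p = 0.0325 and 0.0355), and their list of 12 erythroid markers passed no test (3 fell and 4 when adjusted over the list alone, median -0.02, mean -0.27, adjusted p = 0.259), with a mean of 0.15 on VEGFB_DOX 3 and -0.45 to -0.25 on the other 4.

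No single array moved the total for VEGFB_DOX against PBS by 1.5 times, but the 1170 lower probes became 684 without VEGFB_DOX 2, 711 without VEGFB_DOX 1 and 748 without PBS 4, while cyclic loess gave 2728 probes with another split of 1873 higher and 855 lower. The Hbb-bs call ended without PBS 1, PBS 3, PBS 4, VEGFB_DOX 1, VEGFB_DOX 2 or VEGFB_DOX 4 (values from -0.83 to -0.66), and the Hbb-bt call also without PBS 2, PBS 5 or VEGFB_DOX 5 (values from -0.81 to -0.66), and both ended with a robust variance prior (adjusted p = 0.0855 and 0.089).

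Of the 56 probes higher in DOX than in PBS, 47 were also higher in VEGFB_DOX than in PBS, and of the 24 lower ones 20 were also lower. Among them are Cdkn1a, Phlda3, Ifit3, Oasl2, Usp18, Gbp3, Ifitm3 and Dnaaf3. The same PBS arrays enter both comparisons, and independent lists would share 3.76 and 1.13 probes. For a further reference, equally many probes of smallest p in the same direction were taken from each comparison, whether or not they passed. Ranked so, simulated groups that share controls but no effect shared 33.1 and 14 probes. With the PBS arrays split between the comparisons the medians over 20 splits were 36 (26 to 45) and 9 (5 to 14). In these splits no array entered both comparisons, and each comparison had fewer PBS arrays. Their nearer reference is therefore the independent 3.76 and 1.13, not the simulated groups with shared controls. How far AAV9-VEGF-B moved the genes that the drug had changed was measured with separate DOX arrays for calling genes and for measuring them. Over the 10 ways to call genes with 3 of the 5 DOX arrays, 9 of which called any, the median shift with the vector was -0.24 (SD over the ways 0.35), where a negative value lies nearer to PBS. This value rested on few probes and on 1 array: the ways with DOX 2 among the calling arrays called 0 to 6 probes with shifts of -0.75 to -0.24. The 4 ways without DOX 2 among the calling arrays called 244 to 714 probes with shifts of -0.04 to 0.16, but they measured the shift against DOX 2 and 1 other DOX array. With DOX 2 left out altogether the median shift was -0.12. Without PBS 5 the median was 0.004, and without any 1 other array it lay between -0.42 and -0.04, so the shift was not larger than its own spread. Across probes, which are not independent replicates, the folds of DOX against PBS and of VEGFB_DOX against DOX had a Pearson r of -0.27 and a Spearman rho of -0.31. The same DOX arrays enter both with opposite sign, and simulated groups without effect gave an r of -0.50. The covariance was -0.00675 against -0.00435 in simulation, a difference of -0.00239, and with separate DOX arrays for each comparison the median r over 20 divisions was -0.06, from -0.20 to 0.07. Without DOX 2 and VEGFB_DOX 3 the median over 6 such divisions was -0.15, from -0.24 to -0.05.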

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

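A gap test was applied to the values of each named probe within the 2 groups of 5 arrays of each comparison in which it was named, so not always in all 3 groups: an array stood out when its gap to the nearest other array exceeded 0.71 of the range of its group. Of 277 groups tested, 16 held such an array, where chance alone gives about 1 in 20 groups, or 13.8. They fell on 10 arrays, 5 of them on DOX 2. In each case the share of the range is given with the log2 value of the array and of its nearest neighbour.

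DOX 2 was high in Col4a2 (0.863, at 12.69 against 12.06), Fscn1 (0.806, 9.59 against 8.30), Prkg1 (0.81, 9.21 against 9.04), Prc1 (0.718, 8.37 against 7.48) and Kif23 (0.714, 7.97 against 7.32). In DOX 4 the Notch target Hey1 was low (0.729, 8.99 against 9.42) and Srxn1 high (0.756, 9.28 against 8.97).

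Among the PBS arrays, PBS 3 was low in the interferon-induced genes Gbp3 (0.776, 8.62 against 9.21) and Ifit3 (0.724, 8.98 against 9.69), PBS 1 was low in Dusp23 (0.786, 9.34 against 9.45) and PBS 5 was high in Vim (0.711, 10.21 against 9.94). Among the VEGFB_DOX arrays, VEGFB_DOX 3 was low in the water channel gene Aqp1 (0.88, 12.51 against 13.17), VEGFB_DOX 1 was low in Txlnb (0.848, 8.44 against 8.72), VEGFB_DOX 4 was high in Cpt2 (0.789, 12.94 against 12.79), VEGFB_DOX 2 was low in Ogn (0.741, 11.69 against 11.89) and VEGFB_DOX 5 was high in Kdr, near background (0.714, 7.09 against 6.99).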

How the results depend on the processing

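The settings with normexp background, cyclic loess, the 4 arrays set apart by the second principal component and the leaving out of DOX 2 and VEGFB_DOX 3 were chosen only after the data were seen. The cause of a difference between settings was not tested. Fits to the raw signals and a block for slides were not run, since neither columns nor slides can be given to samples here.

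Of the counts of probes, that for DOX against PBS moved most. It was 80, and 53 without a variance trend, 201 with array weights, 47 genes with the probes of a gene averaged, 143 with the 4 arrays as a block, 1 within the other 11 arrays and 677 without DOX 2 and VEGFB_DOX 3. Leaving out 1 array gave 2 (without DOX 1) to 487 (without DOX 2). Of its 24 named probes that passed, 2 also passed without DOX 1, 7 without DOX 3 and at least 12 without any 1 other array of these groups. VEGFB_DOX against DOX gave 3601 probes with array weights, 1627 to 2597 without 1 array, and VEGFB_DOX against PBS 2008 to 2940. Lists changed numbered 16, 22 and 25 in the 3 comparisons, 2, 5 and 7 with an estimated correlation, and 10 in DOX against PBS with fry.

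The Vegfb fold in VEGFB_DOX against PBS kept its sign and was no longer past the threshold without a filter on dim probes or with only the 2 groups (-0.188 in both, adjusted p = 0.0645 and 0.0534), with cyclic loess (-0.153), within the 11 arrays (-0.163) and without DOX 2 and VEGFB_DOX 3 (-0.193). Without 1 array it ran from -0.205 to -0.16. Against DOX it was -0.203 within the 11 arrays (adjusted p = 0.0539) and -0.245 to -0.19 without 1 array. The correlation of the drug and vector comparisons ran from -0.400 (without DOX 2) to -0.217 (without VEGFB_DOX 3).

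The shift of drug-called genes, -0.238, was 0.00375 without PBS 5. Among named genes a change of sign was seen only in values near 0 that passed no test. In DOX against PBS, Egfl7 was -0.00752 with array weights and -0.0705 without DOX 2 and VEGFB_DOX 3, and ran from -0.0705 to 0.0595 without 1 array, the dim Flt1 probe from -0.032 to 0.0705 and Acta2 from -0.203 to 0.067. In VEGFB_DOX against DOX, Aqp1 was -0.0159 with array weights, -0.0153 and Dcn -0.0235 with probes averaged, and Aqp1 -0.06 within the 11 arrays. Without 1 array Aqp1 ran from -0.0955 to 0.155 and Ogn from -0.165 to 0.023. For single lists, 38 results of leaving out 1 array and 77 of the other settings lost their call while keeping their direction, and 592 and 615 did not change. For named genes these numbers were 120 and 63, with 1548 and 2097 unchanged.

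With the replicate number as a block (replicate block) 81, 2595 and 3135 probes and 15, 23 and 24 lists changed. Of the 80, 2383 and 2841 probes called without the block, 64, 2254 and 2723 were among them. Of the 16, 22 and 25 lists called without it, 14, 22 and 24 kept their call. Of the 24, 50 and 47 named probes that passed without it, 22, 50 and 45 also passed with it. As a set the replicate numbers do not pair the arrays: 7 of 15 pairs of equal number had a residual correlation above 0.1, the range was -0.412 to 0.631, and 5 of 15 arrays matched best with one of their own number. Yet all 3 pairs of number 1 (0.148 to 0.334) and of number 5 (0.32 to 0.631) lay above 0.1, and the 3 arrays of number 5 are among the 4 set apart.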

Other observations

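Further genes in VEGFB_DOX against DOX were chosen after their values were seen. In the p53 list Plk2 rose by 0.52 and Apaf1, an activator of caspases, by 0.52, while Rrm2b and Ddb2, both of DNA repair, fell by 0.39 and 0.24, so targets of p53 went both ways. Among genes of antigen presentation H2-D1 rose by 0.63 and B2m by 0.58. In the lists of fibroblast markers and of macrophage markers Vim rose by 1.53, Col1a1 by 0.86 and Fcer1g by 0.50.

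The tests of the 3 patterns below were chosen only after the patterns had been seen. The counts over other splits of the arrays were chosen before.

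For each comparison 100 of the 126 ways to split its 10 arrays into 5 and 5 were drawn, the real one included. For DOX against PBS only the real split gave as many as 80 probes, with at most 23 in any other. Its 16 lists were reached by 3 splits, the real one included, with 18 as the highest. Its 2 lists with an estimated correlation were reached by no other split (at most 1). For VEGFB_DOX against DOX only the real split gave as many as 2383 probes, with at most 1155 in any other. Its 5 lists with an estimated correlation were reached by no other split (at most 3). Its 22 lists with the preset one were reached by 6 splits, the real one included, with 28 as the highest. The split with 1155 probes set DOX 1, DOX 3, DOX 4, DOX 5 and VEGFB_DOX 5 against the rest, so it kept 4 of 5 DOX arrays apart from 4 of 5 VEGFB_DOX arrays, and why it gave so many was not tested. For VEGFB_DOX against PBS only the real split gave as many as 2841 probes (at most 1 in any other) and 7 lists with an estimated correlation (at most 2). Its 25 lists with the preset one were reached by 4 splits, with 28 as the highest. Since other splits gave more lists with the preset correlation, chance is not excluded for those numbers. Splits that mix the groups take any group difference into their residual spread, which lowers their counts of probes. No correction was made for the number of counts examined.

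In DOX 2 and VEGFB_DOX 3 the p53 target genes stood at the PBS level, at 0.018 and 0.00182. No PBS array read like the other 8 drug arrays on this list: the highest PBS array had 0.0259 and the lowest of those 8 had 0.279. This does not exclude a swap of DOX 2 with a PBS array. VEGFB_DOX 3, labelled as given the drug, also stood at the PBS level, so a low value does not mark a PBS heart. Tissue of a PBS animal was excluded for VEGFB_DOX 3 by its endothelial markers (0.54 against at most 0.0624 in PBS). For DOX 2 it was not settled. Its neutrophil markers (0.254 against at most 0.0456 in PBS) and calcium handling genes (-0.163 against at least -0.0553) lay outside the PBS range. But these 2 lists were chosen after their values were seen, and DOX 2 is among the arrays that gave their calls. Of the 15 lists called beside that of p53, 8 lay inside the PBS range on DOX 2, and its nearest array was PBS 1 (r = 0.995). Neither is particular to DOX 2. The nearest array of DOX 5 was also a PBS array (PBS 4, r = 0.991). On the macrophage list the other DOX arrays lay inside the PBS range as well (0.06 to 0.15 against -0.17 to 0.22). A weaker exposure to the drug may be the cause in DOX 2, where 10 of the 15 other lists called in DOX against PBS lay nearer to PBS than on any other array of its group. Chance gives 3 for an array picked at random. DOX 2 was picked because its p53 target genes lay at the PBS level, and the lists are not independent. VEGFB_DOX 3 had 4 of 15, which decides nothing. No drug level was used here and no biological explanation was tested.

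Endothelial markers were higher with AAV9-VEGF-B. Whether a lower share of cardiomyocytes was the whole cause was not settled. Markers of ventricular cardiomyocytes did not fall as a group in VEGFB_DOX against DOX, but their list test cannot tell a small fall from none. The medians of 11 other cell type lists had a median of 0.016, and 9 of them lay below 0.264, the lower quartile of the endothelial folds. Some of these lists rest on few tested genes, such as those of B cells and of NK and cytotoxic cells with 5 each. Markers of smooth muscle and pericytes, at 0.33, and of fibroblasts lay above this limit. VEGF-B may be the cause, and so may the vector itself without VEGF-B: with 0 control-vector groups the 2 cannot be told apart, and growth of vessels and higher expression per cell stay open as well.

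The arrays PBS 4, PBS 5, DOX 5 and VEGFB_DOX 5 lay apart on the second principal component, which held 19.3% of the variance and is found in all 3 groups. Time of day at collection was not settled: 0 of 13 clock genes deviated one way from their group means in all 4 arrays, where chance gives 1.63. This count lies close to chance, and the group means hold the same 4 arrays. Clock genes such as Dbp also differed between the groups, so the test cannot exclude this cause. A shared processing batch may be the cause: 3 of the 4 arrays carry the number 5 and the 4 stand last in the order of the samples, which goes with it, but 0 arrays have a known slide, so it stays open. With the 4 arrays as a block DOX against PBS gave 143 probes. No biological explanation was tested.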
